A study of Mus musculus with 6 samples.

How the data were processed

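Gene expression was measured on Affymetrix Mouse Clariom S arrays, which carry probe sets for well-annotated mouse genes. Per the labels, total RNA came from whole brains of mice on the FVB background that were fed a high-fat diet (45% w/w) for 12 weeks. The RNA was turned into sense cDNA, fragmented and labelled with biotin. The labels place 3 arrays in a group named LRRK2-GS and 3 in a group named LRRK2-WT, and call them biological replicates without naming the animals. A control diet (12% w/w) is named in the labels, and arrays of that diet were not analysed here, so diet was not compared.

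The deposited table holds 1 log2 value per probe set and array, normalized by the authors, and it was used as deposited. RMA and Affymetrix Power Tools are named in the submitters' processing notes, without versions. The genome build, the annotation version and any filter are not given in the sources used here, so no coordinates are printed. The log2 scale was read from the values, which ran up to 19.93 on most arrays, and the scanner files were not used here. Values this high are unusual for RMA output and the sources do not state the base of the logarithm, so every fold rests on reading the scale as log2. Values were not centred per gene: the medians of the 6 arrays lay between 3.62 and 3.66. All 6 columns were matched to samples by their names. Of the 22206 probe sets, 19572 had 1 gene symbol in the platform annotation, 0 had several and 2634 are unnamed here. The 19572 named probe sets stood for 19505 distinct symbols, and all 19572 gene identifiers matched a mouse reference gene table, which served only for older symbols and gene types. The table held 254 probe sets whose values equalled those of another probe set on all 6 arrays.

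Scanner detection calls were not used here, so a background level was set from probe sets of 1412 olfactory and vomeronasal receptors, which few tissues outside the nose express. It was the 95th percentile of these probe sets on each array, 3.67 to 3.75, so 5% of silent probe sets are expected above it. A gene was counted above background when its mean over the 6 arrays exceeded the mean of the 6 levels. Where no array of a group exceeded its level, the fold is given as a lower limit, against the higher of the level and the measured value on each array of that group. Between 48.4% and 49.3% of probe sets exceeded the level on an array. This definition was chosen after the values were seen. Arrays give no counts, and the number of arrays, 3 per group, limits the precision.

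Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), over all 22206 probe sets and all 6 arrays, with no covariate. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and each adjusted p in the text comes from this fit unless another test is named. Changes are log2 values, GS minus WT, with the standard error of the fit. Gene lists were compared with the other probe sets by camera with a preset correlation of 0.01, adjusted over 45 lists. A list is called where that adjusted p is under 0.05. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives. Fry does not set a list against the other probe sets, so its calls answer a different question from those of camera. Before the data were examined, 27 program lists and 19 marker lists were fixed, along with the tests, the alternatives and the rule for named genes. The sex-linked list was described and not tested. For a gene with several probe sets, lists used the one with the highest mean. Member counts are given over all probe sets tested, and adjusted over the list alone where those differ.

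The named genes were the 12 with the largest change in each direction among those past the threshold. They had to have 1 symbol, to be no predicted gene, RIKEN clone, pseudogene or olfactory or vomeronasal receptor, to exceed the lower quartile of all probe sets in at least 1 group, and to have groups that do not overlap. Lrrk2, up to 4 members with the lowest p among those past the threshold in each program list, and 4 members of each called list in the direction of its call were added. This gave 109 genes, of which the text names a part. Marker genes given as examples of a level are among the first 3 measured members of their lists in the fixed order. Other genes were chosen after their values were seen, and the text says so.

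The scripts were tested on simulated values with the means and spreads of this comparison over 22206 probe sets, of which 200 were changed. At a change of 0.5 on the log2 scale 20.9% of 67 changed probe sets were recovered, at 1 98.5% of 67, and at 2 100% of 66. Of 160 calls, 14 were false. In the data 3860 probe sets were called, and with so many calls the adjusted threshold is less strict than in the simulation. The shares recovered therefore need not hold for the data. Camera called 0 of 45 lists in simulated data without change, and it called the cholesterol synthesis list when its members were shifted by -0.5. The simulated probe sets were drawn independently, so this cannot show how often camera makes false calls where list members vary together. In the data the estimated correlation was 0.23 for the cholesterol synthesis list and 0.17 for the autophagy list.

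The alternatives were the replicate number as a block, leaving out each array in turn, quantile normalization again, centring of each array on its median, a filter on dim probe sets, eBayes with a trend and robust prior, array weights, an unmoderated statistic, other thresholds, averaging per symbol, and the other list tests. Counting identical probe sets once, a minimum change of 1 on the log2 scale, a background level at the 99th percentile and list tests among probe sets above background were added after the data were seen. Further gene lists were also added then, and their camera p-values were adjusted over the added lists alone. The lists of p53 targets, S phase genes, G2 and M phase genes and macrophage lineage genes were written after the values of some of their members had been seen. The lists of integrated stress response genes and endoplasmic reticulum folding genes were written before the values of their members had been looked at, except that of Slc7a11, which had been seen among the genes with large changes.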

Results

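Expression profiles were obtained from 6 arrays, 3 labelled LRRK2-GS and 3 labelled LRRK2-WT, all from mice on a high-fat diet. LRRK2 is a kinase whose mutations cause familial Parkinson disease, and GS stands for the mutant form named by the series. The design asks how brain expression differs between the genotypes under the diet, and the series title names senescence of astrocytes, the permanent arrest of cell division in these glial cells. Values are log2 signals, with a background level of 3.67 to 3.75. Arrays of the same group correlated across probe sets at 0.9959 to 0.9966 (6 pairs), and arrays of different groups at 0.9833 to 0.9844 (9 pairs). The first principal component held 72.4% of the variance. One array, LRRK2-GS replicate 3, was compressed at the top of the scale: its 222 brightest probe sets averaged 17.07, against 17.67 to 17.80 on the other arrays.

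Genes of brain cells were near background on all 6 arrays. Across 10 marker lists of neurons, astrocytes and the oligodendrocyte lineage, 19 of 155 measured genes lay above background (12.3%, exact 95% interval 7.54 to 18.5%), where 5% is expected of silent probe sets. The median level of the 155 genes was 3.04. The astrocyte water channel Aqp4 stood at 3.25 ± 0.14 (SD, n = 6) and the glutamate transporter Slc1a2 at 3.08 ± 0.28, while the folate enzyme Aldh1l1, also an astrocyte marker, stood above background at 3.98 ± 0.19. The vesicular glutamate transporter Slc17a7 stood at 3.09 ± 0.10, the GABA-synthesizing enzyme Gad1 at 3.60 ± 0.13, the dopamine-synthesizing enzyme Th at 3.15 ± 0.10 and the myelin protein Mog at 2.86 ± 0.19. Mbp, a major myelin protein, reached 3.97 ± 0.15 and the Purkinje cell gene Pcp2 4.24 ± 0.11, both above background. By contrast, all 46 cytosolic ribosomal proteins and all 68 oxidative phosphorylation genes lay above background, at median levels of 16.6 and 12.2. Only 4 of the 155 markers exceeded 10, and these were chosen after their values were seen: Foxp1, Aldoc, Prkcd and Cldn11. These levels go against the tissue that the labels name, and the samples are called the arrays labelled GS and WT, or GS and WT arrays, throughout.

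**Figure D1:**
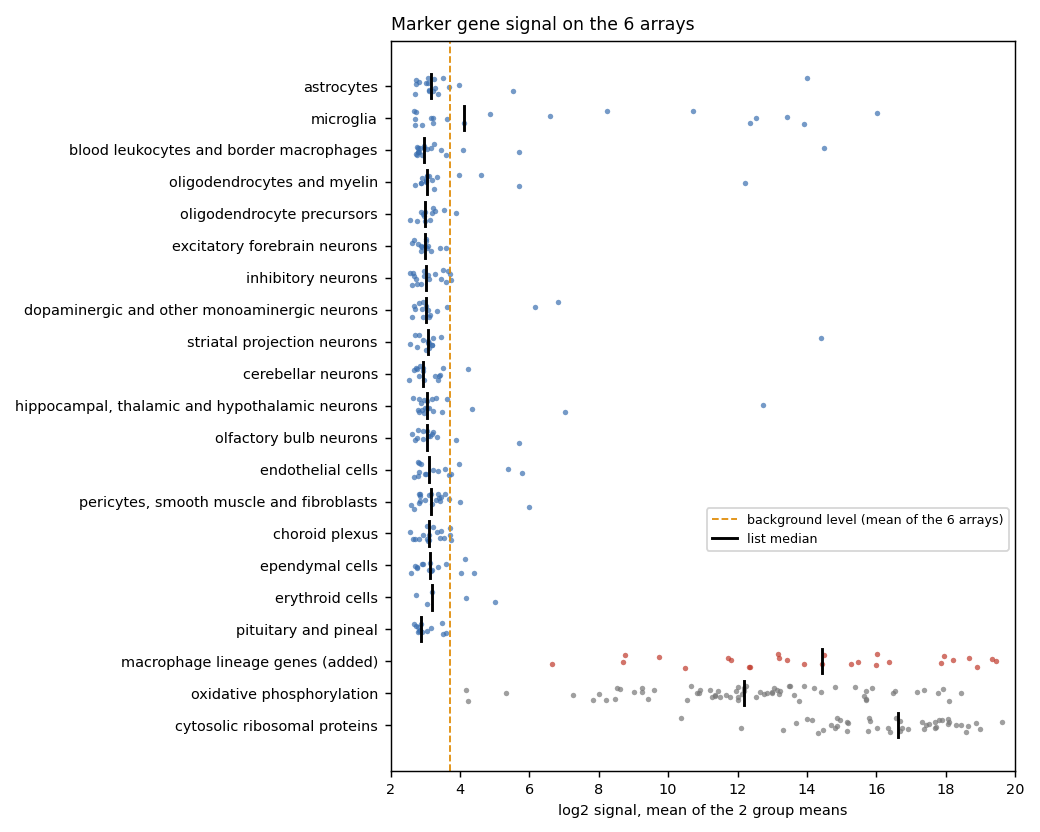
Level of each measured marker gene (log2 signal, mean of both group means, 3 arrays each), with 1 row per list, the list median as a black bar and the background level as a dashed line. Neuron, astrocyte and oligodendrocyte lineage markers had a median level of 3.04, while the macrophage lineage list, added after the data were seen (red), had a median level of 14.4.

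Markers of other cells differed in level. Of the 19 microglia markers, 10 lay above background, but P2ry12 (2.92 ± 0.20, n = 6) and Tmem119 (3.61 ± 0.24), both typical of microglia in the brain, did not. Ptprc, the pan-leukocyte antigen CD45, stood at 14.51 ± 0.36, while the T-cell gene Cd3e stood at 2.83 ± 0.16. Counts above background were 3 of 19 leukocyte and border macrophage genes, 4 of 16 endothelial genes, 2 of 20 pericyte, smooth muscle and fibroblast genes, 2 of 18 choroid plexus genes, 3 of 15 ependymal genes, 2 of 5 erythroid genes and 0 of 13 pituitary and pineal genes. Among the brain cell lists they were 3 of 18 for astrocytes, 4 of 17 for oligodendrocytes, 1 of 13 for their precursors, 0 of 14 for excitatory and 2 of 18 for inhibitory neurons, and 2 of 15 for dopaminergic and other monoaminergic neurons. They were 1 of 15 for striatal and 1 of 15 for cerebellar neurons, 3 of 20 for hippocampal, thalamic and hypothalamic neurons, and 2 of 14 for olfactory bulb neurons. The Y-linked genes Eif2s3y, Kdm5d and Uty lay above background on all 6 arrays, and Eif2s3y was higher on the GS arrays by 0.45 (adjusted p = 0.0395, limma), a call lost when any 1 array other than GS replicate 3 was left out.

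Between the groups, 3860 of 22206 probe sets (17.4%) passed the threshold, 1652 higher and 2208 lower on the arrays labelled GS. The change was at least 2-fold for 640 of the higher and 907 of the lower probe sets, and at least 8-fold for 53 and 50. Among probe sets above background on every array of at least 1 group, 3745 of 10553 (35.5%) passed. The GS and WT values did not overlap for 6619 probe sets (29.8%), where chance gives 10%. Without the compressed array, GS replicate 3, 3567 probe sets passed, 1672 higher and 1895 lower. Quantile normalization turned the balance, with 2053 higher and 2003 lower.

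The 12 named genes with the largest rise on the GS arrays were between 29.1-fold and at least 225-fold higher. Trp53inp1, a p53-induced nuclear protein, reached 11.51 ± 0.08 (SD, n = 3), while no WT array exceeded background (3.28 ± 0.58), so that it was at least 225-fold higher (adjusted p = 1.27e-08, limma). The kinase Plk2 was 175-fold higher, at 13.54 ± 0.38 against 6.09 ± 0.17 (adjusted p = 6.16e-09). Epha2, an ephrin receptor, was at least 67.1-fold higher, with no WT array above background. Eda2r, a receptor of the tumour necrosis factor family, rose 107-fold, the membrane protein gene Prrg4 104-fold, the creatine transporter Slc6a8 44.8-fold, and the thiamine transporter Slc19a2 36.1-fold. Mdm2, the ubiquitin ligase that restrains p53, stood at 16.62 ± 0.49 against 11.18 ± 0.09, a 43.4-fold rise. The T-cell costimulator Cd80 rose 37.2-fold, Gask1b 35.1-fold, and Sesn2 and Ddit4, both stress-induced inhibitors of mTORC1 signalling, rose 35.8-fold and 29.1-fold.

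The 12 named genes with the largest fall were between 12.0-fold and 129-fold lower on the GS arrays. Plk1, the kinase that drives mitosis, stood at 6.69 ± 0.41 on the GS and 13.70 ± 0.02 on the WT arrays, 129-fold lower (adjusted p = 7.64e-09, limma). Kif2c, a kinesin of the centromere, fell by 4.91 on the log2 scale. The cell cycle repressor E2f8 was 26.2-fold lower, and the proliferation marker Mki67 20.4-fold, at 11.10 ± 0.24 against 15.45 ± 0.07. Cdc20 and Fbxo5, an activator and an inhibitor of the anaphase-promoting complex, were 17.3-fold and 13.1-fold lower. Wee1, a kinase that delays mitotic entry, was 17.1-fold lower, the kinetochore gene Nuf2 15.3-fold, cyclin gene Ccna2 14.6-fold, the mitotic kinesin Kif20a 12.4-fold and the kinase Melk 12.0-fold. Tagap, a GTPase-activating protein of immune cells, was 13.9-fold lower. All 24 of these genes kept their direction and stayed past the threshold when any 1 array was left out.

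**Figure D2:**
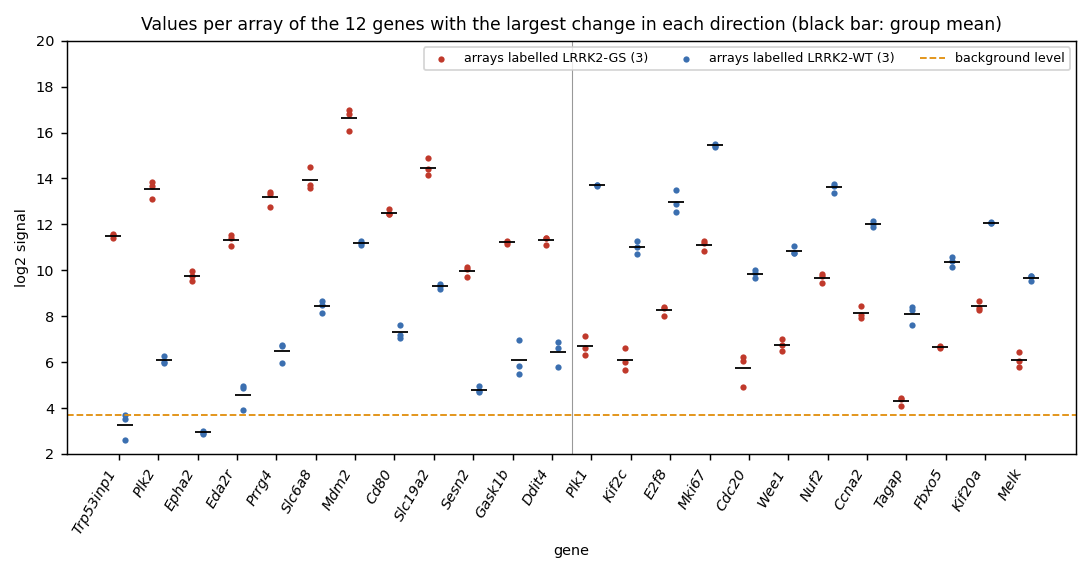
Log2 signal on each array (points, 3 per group) of the 12 genes with the largest change in each direction, with group means as black bars and the background level as a dashed line. The GS and WT points of each gene do not overlap, as for Plk1 with group means of 6.69 and 13.70.

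**Figure D3:**
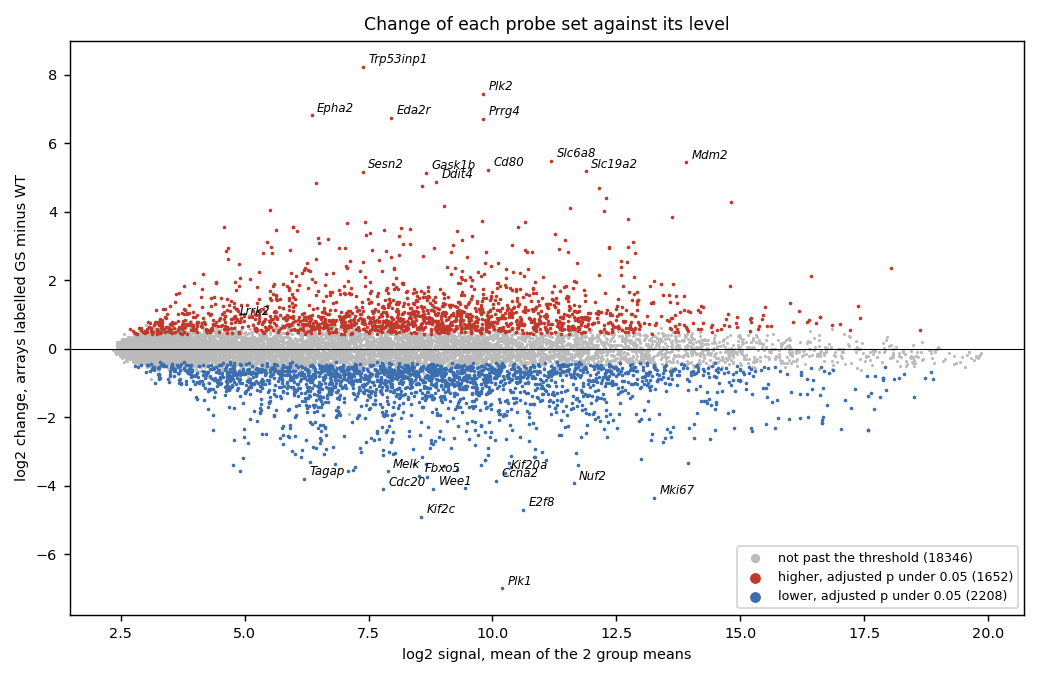
Change (log2, GS minus WT arrays) of each of 22206 probe sets against its level (log2 signal, mean of both group means), with 1652 higher and 2208 lower probe sets past the threshold in colour. Plk2 lies at 7.45, Plk1 at -7.01 and Lrrk2 at 0.88.

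Lrrk2 itself was low on all arrays, at 5.23 ± 0.30 on the GS and 4.35 ± 0.30 on the WT arrays (SD, n = 3 each). It was 1.84-fold higher on the GS arrays (log2 0.88, SE 0.19, adjusted p = 0.00707, limma), a call that the unmoderated statistic did not make (adjusted p = 0.139). The probe set does not read the mutation, so the genotypes were not tested by it. The labels do not say whether the mutant is a mouse or human transgene or a knock-in, so the mouse probe set may not measure the mutant transcript. Of 23 Rab genes and partners of the LRRK2 pathway, 5 rose and 2 fell (5 and 3 adjusted over the list alone). The list was not called (camera adjusted p = 0.607), and 35.5% of all probe sets above background passed the threshold. The LRRK2 substrate Rab12 rose 4.24-fold, the motor adaptor Spag9 (JIP4) 3.61-fold and the early endosome gene Rab5a 2.24-fold, while Rab32 was 2.31-fold lower. Of 16 other Parkinson disease genes, 2 rose and 3 fell (2 and 4 adjusted over the list alone), and 3 rose and 2 fell after quantile normalization or without GS replicate 3. Without GS replicate 2, or without any 1 WT array, 2 rose and 2 fell. The Parkinson disease list was not called either (camera adjusted p = 0.896). The 5 genes of the main fit were Plk2, which phosphorylates alpha-synuclein, and Pla2g6 (2.39-fold higher), and, lower, Vps13c (2.14-fold), the lysosomal channel Tmem175 (1.89-fold) and Fbxo7, which was named after its value was seen (-0.47).

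Among 20 senescence regulators, 6 rose and 10 fell (6 and 11 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0637). It holds inhibitors of the cell cycle beside proliferation genes such as Mki67, which an arrest of division would move in opposite directions. Camera tests for a shared direction, so its result cannot decide for or against senescence. A version of fry that allows changes either way called this list (adjusted p = 4.73e-06), and 32 lists in total. Besides Mdm2, the cell cycle inhibitor Cdkn1a rose 5.15-fold, to 19.23 ± 0.38, close to the top of the scale at 19.93, which can hold a fold down. The other fall with the lowest p besides Mki67 and Ccna2 was in H2ax, the histone variant marked at DNA breaks, 9.32-fold lower. Cdkn2a, which encodes the senescence marker p16, did not exceed background in either group; it was named after its value was seen. Of 38 secreted factors of senescent cells, 16 lay above background, 8 rose and 2 fell (camera adjusted p = 0.0549; adjusted p = 0.419 with an estimated correlation). The list was called higher in 9 of 16 other settings. The protease gene Plau rose 7.73-fold, the chemokine genes Cxcl2 and Ccl4 5.09-fold and 3.81-fold, and Vegfa 2.20-fold, while Cxcl10 was 3.32-fold lower. On these same arrays astrocyte markers were near background, and 4 of 19 microglia markers were lower in the GS group.

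All 19 measured cholesterol synthesis genes fell, and the list was called lower (median change -2.01, camera adjusted p = 1.75e-24; adjusted p = 0.318 with an estimated correlation). Mvd, of the mevalonate pathway, was 8.90-fold lower (9.27 ± 0.22 against 12.43 ± 0.15), Sqle, a rate-limiting enzyme of the later steps, 7.52-fold, lanosterol synthase Lss 6.07-fold and Hmgcs1 5.36-fold. After quantile normalization 18 of the 19 passed. Of 28 genes of lipid uptake, storage and synthesis, 7 rose and 10 fell (7 and 13 adjusted over the list alone; camera adjusted p = 0.241). The falls included the fatty acid synthesis genes Elovl6 (10.4-fold), Fasn (5.72-fold), Scd1 (4.34-fold) and Acaca (3.63-fold). The rises included the lipid droplet protein Plin2 (2.13) and the sterol exporter Abcg1 (2.10), both named after their values were seen. Of 24 fatty acid oxidation and PPAR target genes, 4 fell and 0 rose, among them Acadl (1.95-fold) and Hadh (1.78-fold). Of 22 glycolysis genes 2 rose and 6 fell (3 and 7 adjusted over the list alone, 1 to 3 and 4 to 6 when 1 array was left out), with the lactate transporter Slc16a1 2.74-fold lower and the glucose transporter Slc2a1 2.32-fold higher. The median of the glycolysis list was -0.18 (-0.30 without GS replicate 2, -0.02 without GS replicate 3) and turned to 0.04 after quantile normalization. Of 68 oxidative phosphorylation genes, Ndufs3 alone fell (-0.47, adjusted p = 0.0470), with 14 members at an unadjusted p under 0.05 and 0 called when adjusted over the list alone or by the unmoderated statistic. After quantile normalization 3 of them rose and 0 fell, and when 1 array was left out 0 to 1 rose and 0 to 3 fell.

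The autophagy list was called higher (median change 0.41, camera adjusted p = 0.00282; adjusted p = 0.665 with an estimated correlation), with 13 of 29 members higher and 3 lower (15 and 4 adjusted over the list alone). The cargo receptor Sqstm1 (p62) rose 14.2-fold, from 11.71 ± 0.05 to 15.54 ± 0.42, Gabarapl1 4.59-fold, Wipi2 2.77-fold and Rb1cc1 2.41-fold, while Uvrag was 3.55-fold lower. Of 29 lysosome genes 4 rose and 4 fell, with alpha-galactosidase Gla 4.18-fold and the cholesterol transporter Npc1 2.49-fold higher and Sgsh 2.51-fold lower. After quantile normalization 7 lysosome genes rose and 3 fell, and the list was called higher. Of 26 unfolded protein response genes, 9 rose and 14 fell (11 and 15 adjusted over the list alone). The risers besides Sesn2 and Ddit4 included the transcription factor Atf3, 7.69-fold higher. The fallers included the endoplasmic reticulum co-chaperone Dnajc3, 3.49-fold lower, and the chaperone Hspa5 (-1.41), named after its value was seen. The list's median was -0.55, its mean 0.19, and it was not called (camera adjusted p = 0.761, direction lower; fry direction higher). Of 24 NRF2 antioxidant genes 6 rose and 2 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.0753), led by the cystine transporter Slc7a11 (17.3-fold), haem oxygenase Hmox1 (6.87-fold), Srxn1 (4.80-fold) and Txnrd1 (3.72-fold). Of 14 heat shock genes 2 fell, Hspa4l (-0.58) and Hsph1 (-0.52), and after quantile normalization 1 rose and 1 fell. Without GS replicate 3, 2 heat shock genes rose. The number that fell was 0 without WT replicate 1 and 1 when any other array was left out. Of 19 hypoxia response genes 3 rose and 3 fell (4 and 4 adjusted over the list alone), with Ndrg1 10.2-fold higher and Pdk1 1.56-fold lower; 4 rose and 1 fell without GS replicate 3 or without WT replicate 2, and 3 rose and 0 fell without WT replicate 1.

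**Figure D4:**
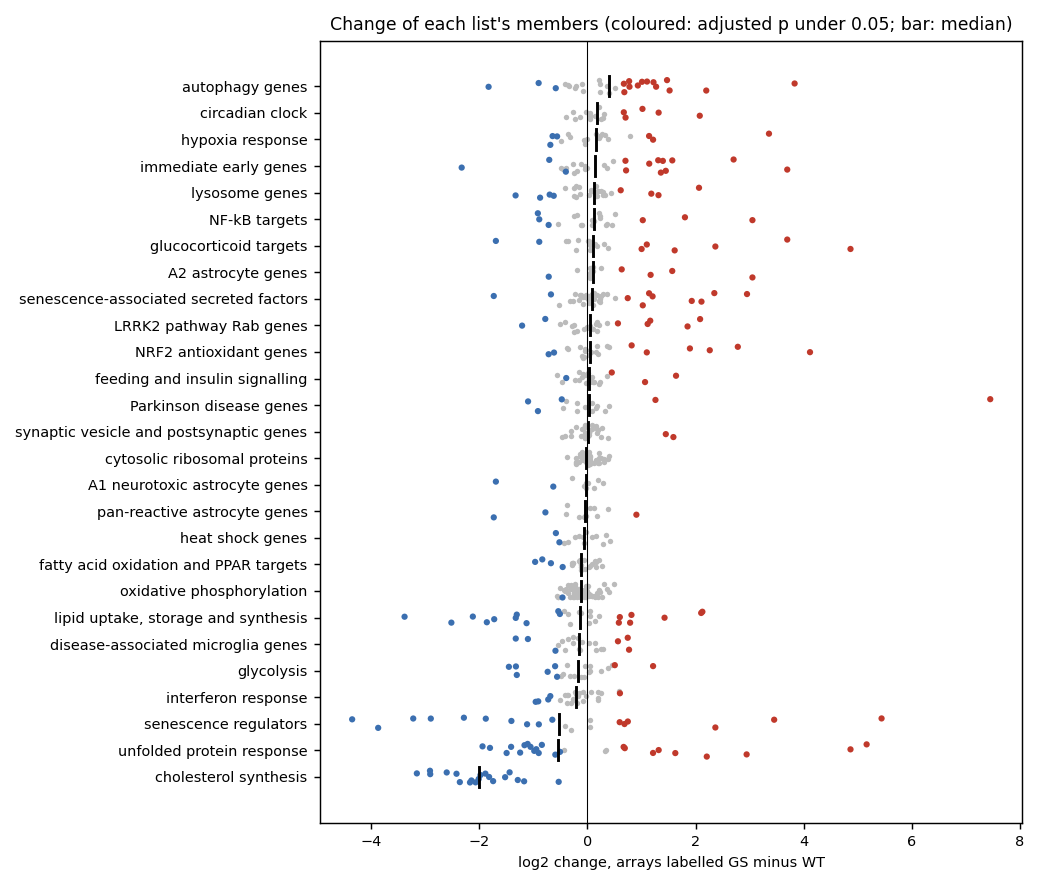
Change (log2, GS minus WT arrays) of each measured member (point) of the 27 program lists, ordered by median (black bar), with members past the threshold in red (higher) or blue (lower). The cholesterol synthesis genes lie to the left of 0 around a median of -2.01, and the autophagy list has the highest median, 0.41.

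The 3 reactive astrocyte lists were compared on arrays where astrocyte markers were near background. Of 13 pan-reactive genes 1 rose and 2 fell (2 and 2 after quantile normalization or without GS replicate 3), with the intermediate filament gene Vim 1.87-fold higher and Cp 1.71-fold lower. Of 10 measured A1 (neurotoxic) genes 2 fell, Fkbp5 (3.23-fold) and Psmb8 (1.55-fold). Of 13 A2 genes 4 rose and 1 fell (camera adjusted p = 0.0637), with the prostaglandin synthase Ptgs2 8.29-fold, Emp1 2.97-fold and Cd109 2.25-fold higher and Stat3 1.64-fold lower. Of 28 interferon response genes 1 rose and 4 fell (2 and 4 after quantile normalization, 0 to 2 and 4 to 5 when 1 array was left out), among them Ifit2 (1.94-fold) and Stat2 (1.88-fold). Of 21 NF-kB targets 3 rose and 3 fell (4 and 3 adjusted over the list alone), with Traf1 3.49-fold and the adhesion molecule Icam1 2.03-fold higher and Bcl3 1.89-fold lower. After quantile normalization 6 NF-kB targets rose and 3 fell. Of 21 disease-associated microglia genes 3 rose and 3 fell, and 1 rose when any 1 array other than GS replicate 3 was left out. Lipoprotein lipase Lpl was 2.51-fold, Cd52 2.14-fold and the receptor Trem2 1.51-fold lower, and Csf1 was at least 1.20-fold higher, above background on 2 of 3 GS arrays and on no WT array. The median of that list was -0.16 (-0.03 without GS replicate 3) and turned to 0.07 after quantile normalization.

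Of the 19 microglia markers 4 fell, all named after their values were seen except Trem2: the fractalkine receptor Cx3cr1 (-2.71), the growth factor receptor Csf1r (-1.27), Selplg (-0.79) and Trem2 (-0.59). The other marker genes past the threshold, also named after their values were seen, were Ptprc (-0.63) and Cd4 (0.53, a call lost when GS replicate 1 or 2 or WT replicate 2 or 3 was left out) among leukocyte genes, Cldn11 (-1.34) among oligodendrocyte genes, Nr4a2 (0.71) among monoaminergic neuron genes, Prkcd (-0.99) and Tcf7l2 (-0.86) among thalamic and related genes, Tshz1 (-1.11) among olfactory bulb genes, and Flt1 (at least 1.23-fold lower, above background on no GS array) and Eng (2.78) among endothelial genes. In the other 11 marker lists, limma called 0 of 164 genes, with 6 at an unadjusted p under 0.05 and 1 called by the unmoderated statistic. Camera called 0 of the 18 marker lists tested. The microglia list had an unadjusted p of 0.0250 there, and fry called it lower (adjusted p = 0.0181).

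Of 26 immediate early genes 10 rose and 3 fell (12 and 6 adjusted over the list alone; camera adjusted p = 0.0549). The phosphatase gene Dusp1 rose 12.9-fold, Ier5 6.51-fold and Junb 2.63-fold, while Egr1 was 5.01-fold lower. Of 20 glucocorticoid targets 6 rose and 2 fell (camera adjusted p = 0.0637). Klf9 rose 3.06-fold beside Dusp1, Ddit4 and Cdkn1a, while the widely used target Fkbp5 fell. Of 18 clock genes 5 rose and 0 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0549), among them Nr1d1 (4.22-fold, above background on 2 of 3 WT arrays), Bhlhe41 (2.49-fold) and Arntl (2.02-fold). Of 27 genes of feeding and insulin signalling, 8 of them above background, 3 rose and 1 fell (2 and 0 adjusted over the list alone, 3 and 0 after quantile normalization), with the transcription factor Foxo3 3.11-fold and Igf1 2.09-fold higher. Of 31 synaptic genes, 10 of them above background, 2 rose, the vesicle protein Vamp2 (3.01-fold) and Homer1 (2.73-fold). Limma called 0 of 46 cytosolic ribosomal protein genes, with 2 at an unadjusted p under 0.05 and 0 by the unmoderated statistic. Their median was -0.02 and their mean 0.01, and after quantile normalization 8 rose, at a median of 0.23. Without GS replicate 3 the median was 0.17, and without GS replicate 2 it was -0.15. Camera called the list higher after quantile normalization and without GS replicate 3.

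Camera called 2 of 45 lists with its preset correlation, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. Fry, which makes no comparison with the other probe sets, called 14. Besides the secreted factors, of the uncalled lists with a camera adjusted p under 0.08, the A2, immediate early and glucocorticoid lists were called higher in 6 of 16 other settings each, the clock list in 5, the NRF2 list in 3, and the senescence regulators lower in 2. Median, mean and test differed in sign also for the astrocyte, oligodendrocyte, monoaminergic neuron and ribosomal protein lists. The labels name biological replicates but no animals, so the source of the spread between arrays is not known. Limma p-values set a change against that spread, with the variance drawn in part from other probe sets. Camera p-values with the preset correlation rest mainly on the spread across genes. They do not show that a list's change would recur on other arrays.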

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

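The settings that count identical probe sets once, require a minimum change, use the 99th percentile as background or test lists among probe sets above background were chosen after the data were seen. Leaving out 1 array in turn gave 3202 to 3567 changed probe sets, 1343 to 1672 higher and 1844 to 2058 lower, a Lrrk2 change of 0.76 to 1.05, and 2 to 6 called lists. The unmoderated statistic passed 1648 probe sets, 666 higher and 982 lower, of which 1590 were among the 3860, and it ended the call of Lrrk2 (0.88, adjusted p = 0.139; 0.00218 to 0.0371 in its other settings). With 4 residual degrees of freedom and no shared variance it has less power by construction. Requiring a change of at least 1 on the log2 scale left 1547 probe sets, 640 higher and 907 lower. The count of changed probe sets stayed within 1.5 times under all other settings, from 3431 with a 1.5-fold change and unadjusted p under 0.05 to 4739 at adjusted p under 0.1. Quantile normalization gave 2053 higher and 2003 lower (49.4% lower, against 57.2%).

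The number of called lists moved most. It was 2 with the values as deposited, 10 after quantile normalization, 5 after centring, 5 among probe sets above the median level, 12 for list members above the median level, 6 among probe sets above background, 14 with fry and 0 with an estimated correlation. It was 4 without GS replicate 1, 5 without GS replicate 2, and 6 without GS replicate 3. The cholesterol synthesis and autophagy lists were called in each of these settings except with an estimated correlation. The cause was not tested for the other lists. Neither called list turned its direction, nor did any named gene. Of the 27 program lists, 4 that were not called had medians that changed sign after quantile normalization (glycolysis, disease-associated microglia, oxidative phosphorylation and ribosomal proteins), and 8 had medians on both sides of 0 when arrays were left out in turn. Of 108 named genes besides Lrrk2, 28 lost the threshold in at least 1 setting, 27 of them with the unmoderated statistic, and 7 at most when an array was left out. Marker genes of neurons, astrocytes and the oligodendrocyte lineage above background numbered 19, and 13 at the 99th percentile.

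Arrays of the same replicate number did not deviate together (correlations 0.02, -0.03 and 0.01), so the number was not taken to pair them. With the replicate number as a block, 3814 probe sets passed, 3614 of them shared, Lrrk2 kept its call (adjusted p = 0.0170) and the same 2 lists were called. Genes near background and the 35 probe sets above 19 on any array may have changes held down by the ends of the scale, which was not tested.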

Other observations

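The lists of p53 targets, cell cycle phases and macrophage genes and the tests on them, the test of scaling, the test without GS replicate 3 and the counts over splits were chosen only after the results were seen, as was the repeat of the stress response test without Slc7a11 and Cebpb. The test of the stress response branches was written before its result was seen, when the value of 1 member, Slc7a11, was known.

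Genes of the cell cycle moved almost as a block. Of 41 S phase genes, 39 fell and 0 rose on the GS arrays (median change -1.51, camera adjusted p = 2.89e-35; adjusted p = 0.00352 with an estimated correlation). These included the replication licensing genes Mcm2 (-1.68) and Mcm5 (-1.51) and the ribonucleotide reductase gene Rrm2 (-2.52). Of 53 G2 and M phase genes, 50 fell and 2 rose (median change -2.19, camera adjusted p = 6.20e-43; adjusted p = 0.00352 with an estimated correlation). The mitotic kinases Aurka (-3.04) and Cdk1 (-2.67) were among those that fell, and the 2 that rose were Gtse1 (3.17) and Psrc1 (2.67), both known as p53-inducible genes. Of the 12 genes named for the largest falls, 5 are on these lists.

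Of 72 p53 targets, 36 rose and 13 fell (median change 0.56, camera adjusted p = 2.12e-11; adjusted p = 0.0551 with an estimated correlation). Of the 12 genes named for the largest rises, 7 are on this list, and the remaining 65 targets had a median of 0.36, with 29 higher and 13 lower. The death receptor gene Tnfrsf10b (4.83), Ccng1 (4.29), Zmat3 (3.55), Pmaip1 (3.06) and Phlda3 (at least 14.3-fold, above background on no WT array) rose, while Sesn1 (-3.26), Polh (-2.44), Dram1 (-1.30) and Tigar (-0.58) fell. Of 27 macrophage lineage genes 2 rose and 11 fell (0 to 3 and 9 to 10 when 1 array was left out), with the Fc receptor Fcgr1 lowest (-2.90). That list's median was -0.37 and camera called it lower (adjusted p = 0.000269; adjusted p = 0.26 with an estimated correlation), and its median was -0.13 after quantile normalization and also -0.13 without GS replicate 3.

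For the near absence of brain cell transcripts, low signal is argued against, since 100% of ribosomal protein and respiratory chain genes lay above background. A candidate explanation is that the table holds cells of the macrophage lineage in place of brain: 100% of 27 macrophage genes (exact 95% interval 87.2 to 100%) lay above background at a median level of 14.4, with Spi1 at 19.24 and 19.64, Lyz2 at 19.14 and 19.55 and Cd14 at 18.06 and 17.81 on the GS and WT arrays. That list was written after the levels of some of its members were seen. Of its 27 genes, 8 are on the fixed microglia, leukocyte or disease-associated microglia lists. Of the lists fixed before, 3 of 19 leukocyte and border macrophage genes and 10 of 19 microglia markers lay above background. The former list was fixed with T-cell genes, but also with macrophage genes such as Mrc1, Cd163, Lyve1 and Pf4. Its low count, which includes Ptprc, is therefore a limit on the macrophage explanation. Of the disease-associated microglia genes, 19 of 21 lay above background, at a median level of 12.96. That fixed list shares genes such as Ctsd with the lysosome list, where 29 of 29 lay above background. With 12.3% of the brain cell markers above background, poorly responding probe sets stay open for the markers at background, since no array known to hold brain RNA was at hand. What the samples were, and whether their labels belong to another table, was not tested, so no change in this comparison can be ascribed to brain, astrocytes or the LRRK2 genotype.

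Lower cell cycle and sterol genes with higher p53 targets form the second pattern. Array-wide scaling is argued against by bright genes outside the pattern: median changes were -0.02 for ribosomal protein and -0.13 for oxidative phosphorylation genes. The median of the G2 and M phase genes was -2.11 after quantile normalization. That test decides little, since the array medians already lay between 3.62 and 3.66 and the step could move values only slightly. The compressed array is argued against too, as the cholesterol synthesis median was -1.93 without GS replicate 3. That p53 targets were induced as a set cannot be told apart from a choice of list made after the top genes were seen: the median was 0.56, but the call was lost with an estimated correlation. A difference in the state or handling of the sampled cells, and the genotype itself, stay open and untested.

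The unfolded protein response list held members moving both ways, and genes outside that list were used to follow this up. Of 27 other integrated stress response genes, mostly ATF4 targets, 12 rose and 2 fell (median 0.31, or 0.16 without WT replicate 3, camera adjusted p = 1.86e-05; adjusted p = 0.197 with an estimated correlation). Of 32 other endoplasmic reticulum folding and transport genes, 0 rose and 14 fell (median -0.45, camera adjusted p = 1.43e-08; adjusted p = 0.166 with an estimated correlation). The medians differed by 0.756 (permutation test across genes, which are not independent replicates, p = 1e-05, the smallest that 100000 permutations can give). Without Slc7a11 and Cebpb, which the macrophage list also holds, the difference was 0.720 (permutation p = 3e-05). This is consistent with higher ATF4 branch genes beside lower folding branch genes, as a hypothesis.

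Among the 10 splits of the 6 arrays into 3 and 3, the labelled split passed 3860 probe sets, 1 of the 10 passed that many, and the highest of the others was 0. With 10 splits a share under 0.05 cannot be reached.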
